A study of Rattus norvegicus with 119 samples.

How the data were processed

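RNA from the hippocampus of 119 rats was measured on 1-colour Affymetrix Rat Gene 1.0 ST arrays, 1 array per animal. The labels give 3 strains (Fischer, Long Evans and Sprague Dawley), both sexes, and 5 treatments: control food, or food with lead acetate at 250 or 750 ppm in a perinatal or a postnatal period. Perinatal exposure ran, per the labels, from 10 days before breeding of the dams until weaning, and postnatal exposure from birth to postnatal day 45. All tissue was collected on postnatal day 55. The 30 groups had 4 animals each, except the Sprague Dawley male controls, which had 3. Groups were read from the labels and never from the measured values. Litters were not given in the labels, so animals were treated as independent.

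The deposited values were log2 intensities per probe set, which the authors made with RMA and Partek (versions, order of steps and any batch correction were not stated). They covered 29214 probe sets, no missing value, and a range from 2.293 to 14.18. Array medians ranged from 7.355 to 7.566, and the correlations of array pairs ranged from 0.9789 to 0.9975. No 2 arrays were identical. Control probe sets could not be told from the others and stayed in. The number of animals per group limited the precision. Of the probe sets, 15310 carried exactly 1 gene symbol (14506 symbols), 323 carried several and 13581 carried none. Symbols were matched to the GRCr8 annotation by gene identifier for 15279 probe sets. That annotation was also used to find neighbouring genes. For 319 probe sets the values were identical to those of another probe set in every array.

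Group means were fitted with limma 3.58.1 in R 4.3.3, with the package data.table (version 1.17.8) for reading in. Figures were drawn with matplotlib 3.10.9. Moderated tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all probe sets within a contrast. A probe set was called at an adjusted p under 0.05. Each of the 8 exposed groups of a strain was compared with the controls of that strain and sex, which gave 24 contrasts. The 4 contrasts of a strain and sex shared their controls, so their results were not independent. The mean of the 8 effects per strain, the sex difference of that mean, the dose contrast and the period contrast were fitted within strain. Strain differences of the mean effect, and strain and sex contrasts of the control animals, came from 1 fit of all 30 groups. Errors beside log2 differences are standard errors from limma. The contrasts were tested on simulated data, with independent noise of the real spread of each strain. In a contrast of 4 against 4 Long Evans males, 17.9% of the shifts of 0.25, 68.7% of those of 0.5 and 97% of those of 1 (log2) were called.

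Named genes followed a rule that was fixed before the data were examined, as were the design, 28 gene lists and the first alternatives. Only probe sets with exactly 1 symbol were eligible. The rule took the 10 highest and 10 lowest called genes of each strain mean, the 3 highest and 3 lowest of each of the 24 contrasts, and the 5 highest and 5 lowest of every other contrast. It also took up to 4 members with the smallest p-values, called or not, of each list whose shift was called. Alad, Grin1, Grin2a, Grin2b, Bdnf, Dnmt1, Dnmt3a, Mt1, Mt3, Hmox1, Gfap and Ttr were taken whatever their result. Another gene of the rule is not reported here. A few other genes and probe sets are named below as chosen after their values were seen.

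The lists covered glutamate receptors, the GABA system, synaptic vesicle release, activity-induced immediate early genes, myelin and oligodendrocytes, astrocytes, microglia, interferon response, metal handling, NRF2, heme synthesis, heat shock, DNA methylation and chromatin regulators, glucocorticoid-induced genes, the circadian clock, neurogenesis, principal neurons, thyroid hormone targets, ribosomal proteins, oxidative phosphorylation and sex-chromosome genes. Markers of tissue that a hippocampal dissection could carry made up the other lists: choroid plexus, meninges, blood vessels, red blood cells, thalamus, striatum and neocortex. Lists were tested with camera (limma) at its preset inter-gene correlation of 0.01, and again with an estimated correlation. Their p-values were adjusted within each family of contrasts. The lists shared some genes with each other (6 of the 16 probe sets of the glucocorticoid list stood in another list), and several marker genes are also expressed in hippocampus itself.

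The alternatives set before the data were examined were 1 fit for all 119 arrays, a further quantile normalization, only probe sets above the 40th percentile of mean level, array weights, the choroid plexus score as a covariate, leaving out each animal in turn, and the estimated correlation for lists. Others were chosen after the data were seen. Within each group the animals were parted by the number in their labels into lower and upper label numbers, which served as a block per strain, and the fits were also run in each of these sets alone. The contrast of all females with all males, and the list tests for dose, period and differences between strains and sexes, were also added then.

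A check of sex labels was added after levels had been seen. An array went against its label when X-linked Eif2s3, and the mean of Ddx3x and Pbdc1, both lay on the other sex's side of the midpoint within its strain and label-number set. Looser versions of this rule were looked at first. The counts without the 8 arrays it named had not been seen when it was fixed. All arrays kept their labels and stayed in the reported values, and the fits were repeated without those 8. The arrays carried 2 Y-linked probe sets, which were not used for the check.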

Results

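Hippocampal gene expression was measured in rats on postnatal day 55, after perinatal or postnatal lead at 250 or 750 ppm in food, or control food. The 30 groups by strain, sex, period and dose had 4 animals each, or 3 in the Sprague Dawley male controls. Values were log2 levels of 29214 probe sets. The number of arrays limited the precision.

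The arrays parted by strain and, in Fischer, by label number. The first principal component held 20.5% of the variance, and Long Evans arrays scored from -23.0 to -13.9 on it, apart from all others. Fischer arrays fell into separate sets on this component, which followed the numbers in their labels: animals with the lower numbers of each group scored from -3.6 to 6.2 and those with the upper numbers from 17.6 to 28.9. Sprague Dawley arrays scored from 0.6 to 14.8. Between lower and upper label numbers, 17793 probe sets differed in Fischer, 5527 in Sprague Dawley and 29 in Long Evans. Among the Fischer genes, chosen after their values were seen, centrin Cetn2 was higher in the upper numbers by 1.43 ± 0.03 (log2, SE; adjusted p = 1.5e-28) and the apoptosis inhibitor Bcl2 was lower, at -0.98. Each group held animals of both sets. Groups had their own runs of successive label numbers, and most contrasts compared different runs. The block, which ranks numbers within a group, cannot adjust for that. Counts that moved by over 1.5 times and named genes that lost their call with lower and upper label numbers as a block are given with the result.

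**Figure D1:**
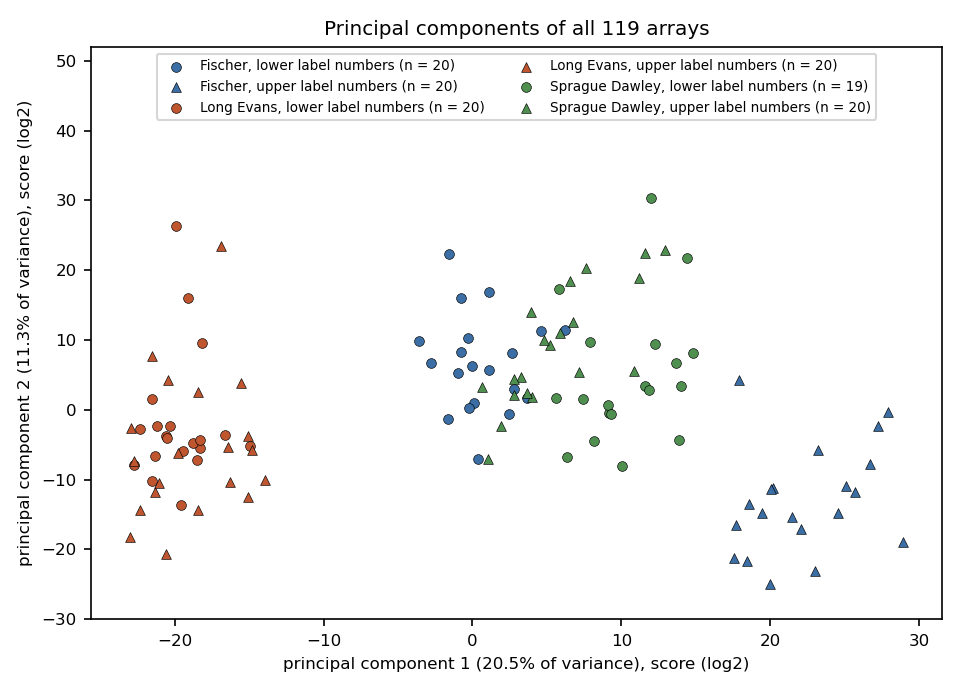
Scores of all arrays on principal component 1 (x axis, 20.5% of variance, log2 units) and principal component 2 (y axis, 11.3% of variance, log2 units), with 1 point per animal. Fischer animals with upper label numbers lie at 17.6 to 28.9 on the x axis, apart from Fischer animals with lower numbers at -3.6 to 6.2.

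Apart from 8 arrays, the X-linked translation factor Eif2s3 was higher in females than in males within each strain and label-number set. In Long Evans animals with lower label numbers, for example, males lay between 11.23 and 11.41 and females between 11.72 and 11.86. In those 8 arrays Eif2s3 and the mean of the X-linked genes Ddx3x and Pbdc1 both lay on the side of the other sex. These were Long Evans male control 4 (Eif2s3 11.79), Long Evans female controls 1 (11.40) and 3 (11.40), Sprague Dawley female control 2 (11.67), Sprague Dawley male perinatal 750 ppm replicate 4 (11.84), male postnatal 750 ppm replicate 2 (11.99) and female postnatal 750 ppm replicates 2 (11.50) and 4 (11.40). None was in Fischer. The labels were kept. Counts and calls that changed likewise without these arrays are given with the result.

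**Figure D2:**
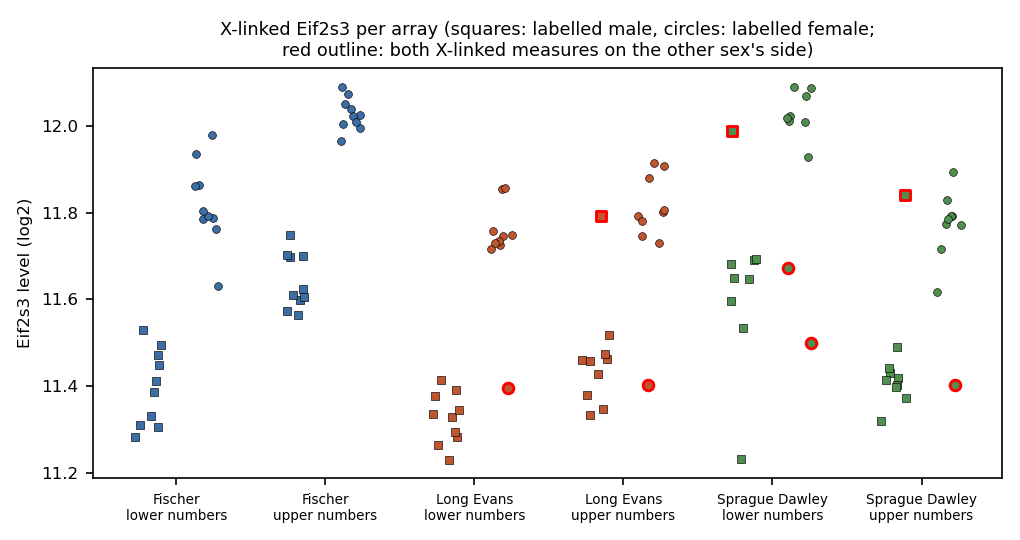
Eif2s3 level per array (y axis, log2) by strain and by lower or upper label numbers (x axis), with squares for labelled males, circles for labelled females and red outlines for the 8 arrays against their label. Apart from those 8, males lie below females within each strain and label-number set, for example at 11.33 to 11.52 and 11.73 to 11.92 in Long Evans animals with upper numbers. The 8 were picked partly by Eif2s3 itself, which favours this separation.

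The genes that differed between lead-exposed and control animals of a strain and sex varied by strain. In Long Evans rats the lipid droplet assembly factor Ldaf1 was above control in all 8 exposed groups, the Fc receptor-like gene Fcrl2 was lower in several, and single groups showed changes in Alb, Gpd1, Mx2, Fbln2 and Cd93. In Sprague Dawley males the acute-phase serine protease inhibitor Serpina3n was lower in all 4 exposed groups. In Fischer rats the few calls included the activity-induced genes Fos and Dusp1. Counts of called probe sets were 99 over the 8 Long Evans contrasts (70 higher, 29 lower), 19 over the 8 Sprague Dawley contrasts (9 higher, 10 lower) and 5 over the 8 Fischer contrasts (4 higher, 1 lower). With label numbers as a block they were 86, 26 and 11. A probe set called in several contrasts counts in each, and the 4 contrasts of a strain and sex shared their controls. These counts by strain were not compared with each other directly, since the mean effects were (below).

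**Figure D3:**
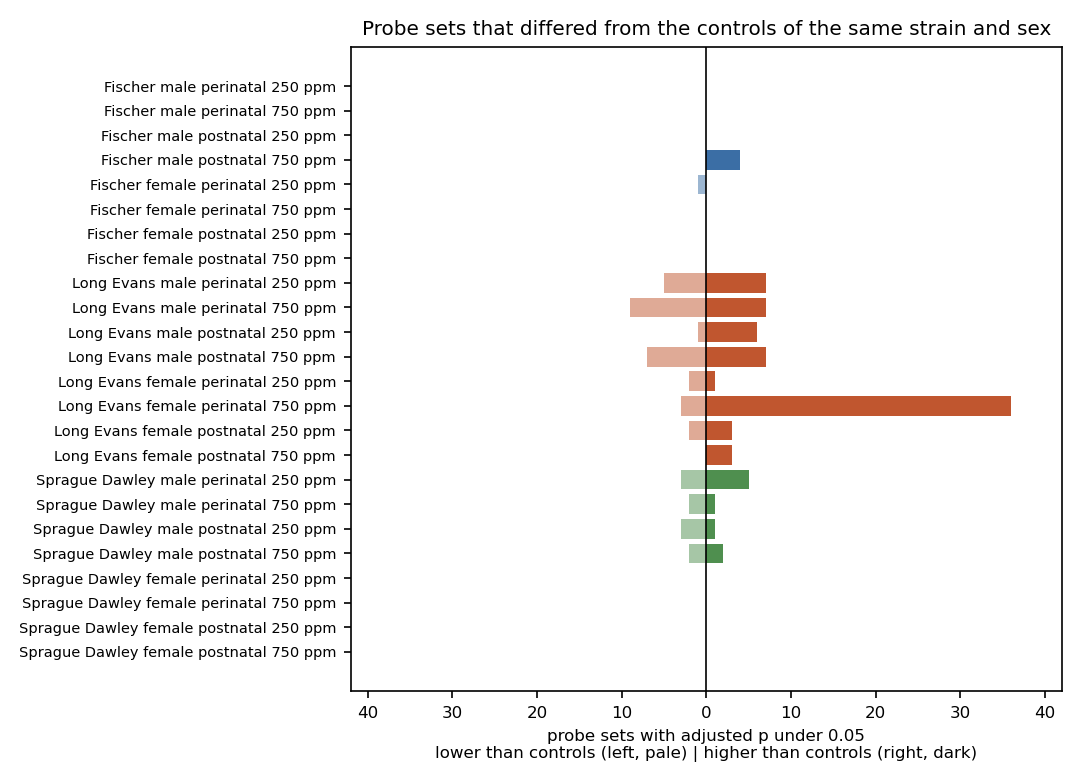
Number of probe sets (x axis) with an adjusted p under 0.05 that were higher (right, dark) or lower (left, pale) than in controls, for each of the 24 exposed groups (y axis). The bar for Long Evans females at perinatal 750 ppm is the longest, with 36 higher and 3 lower.

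In Fischer males after postnatal lead at 750 ppm, 4 probe sets rose. The vascular early response gene Apold1 rose by 1.24 ± 0.18 (log2, SE; n = 4 against 4; adjusted p = 0.0024), the MAP kinase phosphatase Dusp1 by 0.97 ± 0.17 (adjusted p = 0.020) and the transcription factor Fos by 0.57 ± 0.10 (adjusted p = 0.016), beside 1 probe set with no gene symbol at 0.54. The mean of the immediate early gene list was 0.26 higher, with 2 called members and 7 adjusted over the list alone, but its shift had an adjusted p = 0.49 with an estimated correlation. The choroid plexus list was 0.60 higher in the same contrast. Without male control 1 or 3, or without replicate 1 or 2 of the exposed group, the count was 1, and with label numbers as a block it was 9. In Fischer females after perinatal lead at 250 ppm the tubulin-binding gene Tppp3 was lower by -0.35 ± 0.06 (adjusted p = 0.039), the only call, but it was lost with the choroid plexus score as a covariate (adjusted p = 0.12). That count was 0 without female control 1, 2 or 4 or exposed replicate 2, 3 or 4, 2 without female control 3, and 2 with label numbers as a block. In the other 6 Fischer contrasts limma called 0. Fewer than chance gives had an unadjusted p under 0.05: 327, 1180 and 429 (males) and 807, 862 and 1084 (females).

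In Long Evans males Ldaf1 rose in all 4 exposed groups, by 1.02 ± 0.12 (log2, SE; n = 4 against 4; adjusted p = 3.1e-05) at perinatal 250 ppm, 0.60 ± 0.12 (adjusted p = 0.043) at perinatal 750 ppm, 0.79 ± 0.12 (adjusted p = 0.0035) at postnatal 250 ppm and 0.93 ± 0.12 (adjusted p = 2.1e-04) at postnatal 750 ppm. Fcrl2 fell by 1.23 ± 0.20 at perinatal 250 ppm and by 1.45 ± 0.20 at postnatal 750 ppm (adjusted p = 0.0037 and 4.1e-04). At perinatal 250 ppm the mitochondrial LYR-motif gene Lyrm1, a neighbour of Ldaf1 in the genome, rose by 0.42 ± 0.07, the sperm-associated Adam32 rose by 0.57 ± 0.11, and the growth factor Bmp3 and the lipid droplet hydrolase Ldah fell by 0.91 ± 0.15 and 0.69 ± 0.11. At perinatal 750 ppm the glycosyltransferase B3gnt4 rose by 0.55 ± 0.11 and the transcription factor Tfcp2l1 by 0.35 ± 0.07, while the interferon-induced GTPase Mx2 fell by 1.68 ± 0.34, the matrix gene Fbln2 by 0.93 ± 0.16 and the endothelial receptor Cd93 by 0.57 ± 0.09. The oxidoreductase Pyroxd2 rose by 0.72 ± 0.14 and 0.83 ± 0.14 after postnatal 250 and 750 ppm. The ciliary gene Rpgr rose by 0.53 ± 0.09 at postnatal 250 ppm. At postnatal 750 ppm the transketolase-like Tktl1 rose by 1.05 ± 0.20, and the pheromone receptor gene Vom2r44 and the retinoic acid-binding protein Crabp1 fell by 0.88 ± 0.14 and 0.74 ± 0.14.

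Counts in these males were 12 (7 higher, 5 lower) at perinatal 250 ppm, 16 (7 higher, 9 lower) at perinatal 750 ppm, 7 (6 higher, 1 lower) at postnatal 250 ppm and 14 (7 higher, 7 lower) at postnatal 750 ppm. Without the 3 Long Evans arrays against their sex label (male control 4 among these controls) they were 9, 0, 3 and 11. All 6 genes named for perinatal 750 ppm lost their calls then (adjusted p from 0.054 to 0.14), as did Adam32 at perinatal 250 ppm (0.068), Pyroxd2 at postnatal 250 ppm (0.13) and Tktl1 at postnatal 750 ppm (0.090). Calls ended with label numbers as a block for Ldaf1, B3gnt4 and Mx2 at perinatal 750 ppm (adjusted p = 0.053 each), Adam32 at perinatal 250 ppm (0.060) and Pyroxd2 at postnatal 250 ppm (0.056). At perinatal 750 ppm the choroid plexus list was 0.71 lower than in controls (adjusted p = 0.82 with an estimated correlation), and the count was 6 with its score as a covariate and 6 with array weights. It was 0 without male control 1, 1 without exposed replicate 1 or 2, 4 without male control 2 or 4, 6 without male control 3 and 9 without exposed replicate 4. At postnatal 250 ppm it was 1 without male control 2, 2 without male control 1 or 3 or exposed replicate 3, 3 without exposed replicate 2 and 4 without male control 4 or exposed replicate 1 or 4. At postnatal 750 ppm it was 7 without male control 1 or 2 or exposed replicate 1 or 2.

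In Long Evans females after perinatal lead at 750 ppm, albumin (Alb) rose by 1.03 ± 0.13 (log2, SE; n = 4 against 4; adjusted p = 1.3e-05), the glycerol-3-phosphate dehydrogenase Gpd1 by 1.05 ± 0.20 (adjusted p = 0.017) and the thiamine transporter Slc19a3 by 0.96 ± 0.18 (adjusted p = 0.016). The meninges list averaged 9.134 there against 8.785 in controls, and the choroid plexus list 8.562 against 9.088. The choroid plexus list averaged 8.065 at perinatal 250 ppm, and the meninges list 9.217 at postnatal 750 ppm. With an estimated correlation, 0 list shifts were called in these contrasts. Ldaf1 rose by 0.75 ± 0.12 and 0.74 ± 0.12 after postnatal 250 and 750 ppm (adjusted p = 0.0085 and 0.012). At postnatal 250 ppm the endosomal GTPase Rab7b rose by 0.51 ± 0.09 and Fcrl2 fell by 1.08 ± 0.20 (adjusted p = 0.035). At perinatal 250 ppm the 3 calls carried no gene symbol and were chosen for mention after their values were seen, at 0.81, -0.38 and -0.45. Counts were 3 (1 higher, 2 lower), 39 (36 higher, 3 lower), 5 (3 higher, 2 lower) and 3 (3 higher) in the order perinatal 250 and 750 ppm, postnatal 250 and 750 ppm. Without the 3 Long Evans arrays against their sex label (female controls 1 and 3 among these controls) they were 0, 5, 1 and 1. Alb kept its call (adjusted p = 0.011), and Ldaf1 did not in either postnatal group (adjusted p = 0.076 and 0.11). Gpd1 (0.35), Slc19a3 (0.32), Rab7b (0.16) and Fcrl2 (0.44) also lost theirs. At perinatal 750 ppm the count was 16 without female control 1, 17 without exposed replicate 3 or 4, 21 without female control 4 and 25 without female control 3 or exposed replicate 2. At perinatal 250 ppm it was 1 without female control 1 or 4 or exposed replicate 3, and 1 with label numbers as a block. At postnatal 250 ppm it was 2 without female control 2 or exposed replicate 3 or 4, and 3 without female control 1 or 3 or exposed replicate 1 or 2. At postnatal 750 ppm it was 1 without exposed replicate 2 or 3.

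In Sprague Dawley males Serpina3n fell in all 4 exposed groups, by 0.99 ± 0.16 (log2, SE; n = 4 against 3; adjusted p = 0.0054) and 1.08 ± 0.16 (adjusted p = 0.0020) after perinatal 250 and 750 ppm, and by 0.92 ± 0.16 (adjusted p = 0.022) and 1.13 ± 0.16 (adjusted p = 8.5e-04) after postnatal 250 and 750 ppm. At perinatal 250 ppm the matrix-associated gene Ccn1 rose by 1.19 ± 0.19, and the activity-induced genes Arc and Nr4a1 rose by 0.89 ± 0.17 and 0.75 ± 0.14. The immediate early gene list was 0.31 higher there, with 2 called members and 11 adjusted over the list alone, and its shift had an adjusted p = 0.077 with an estimated correlation. The meninges list mean was -0.22 there (adjusted p = 0.86 with an estimated correlation) and the choroid plexus list mean -0.12. At postnatal 750 ppm Fcrl2 rose by 1.07 ± 0.18 and the interferon-induced Ifi27 by 0.61 ± 0.11, while the class I histocompatibility gene RT1-M1-2 fell by 1.07 ± 0.18. Counts were 8 (5 higher, 3 lower), 3 (1 higher, 2 lower), 4 (1 higher, 3 lower) and 4 (2 higher, 2 lower). After a further quantile normalization fewer were called at perinatal 250, postnatal 250 and postnatal 750 ppm, so some of these calls were lost (counts given further below). The remaining calls in the 3 smaller contrasts had no gene symbol and were chosen for mention after their values were seen: 0.45 and -0.33 at perinatal 750 ppm, and 0.47, -0.53 and -0.29 at postnatal 250 ppm. At perinatal 250 ppm the count was 0 without male control 3, 3 without male control 2, 4 without male control 1 or exposed replicate 3, and 5 without the arrays against their sex label. At perinatal 750 ppm it was 1 without male control 2 and 5 without exposed replicate 4. At postnatal 250 ppm it was 0 without male control 3, 1 without male control 1 or 2 or exposed replicate 3, and 2 without exposed replicate 1. At postnatal 750 ppm it was 0 without male control 3, 1 without male control 1 or 2 or exposed replicate 3, and 2 without exposed replicate 4. Fcrl2 at postnatal 750 ppm (adjusted p = 0.13) and Arc and Nr4a1 at perinatal 250 ppm (0.083 and 0.056) lost their calls without the arrays against their sex label.

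In Sprague Dawley females limma called 0 probe sets in each of the 4 contrasts. Fewer than chance gives had an unadjusted p under 0.05 (1346, 796, 758 and 667). Serpina3n was lower by values that did not pass, at -0.78, -0.64, -0.58 and -0.74 (adjusted p = 0.14, 0.92, 1 and 0.37). Without the arrays against their sex label it did pass, at -0.99, -0.85, -0.79 and -0.92 (adjusted p = 3.6e-04, 0.0057, 0.010 and 0.033), and the counts were 4, 2, 2 and 1. The interferon-induced Ifi27 (0.55, adjusted p = 0.031) and the microglial membrane gene Tmem119 (-0.47, adjusted p = 0.020) were then called at perinatal 250 ppm. Leaving out female control 2 by itself gave counts of 4, 2, 2 and 2. Leaving out exposed replicate 4 gave 2 at perinatal 250 ppm, leaving out exposed replicate 2 gave 1 at perinatal 750 ppm, and label numbers as a block gave 2 at perinatal 250 ppm. In that group the choroid plexus list was 1.23 higher than in controls.

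The mean of the 8 lead effects per strain pooled sexes, periods and doses. In Long Evans rats Ldaf1 rose by 0.71 ± 0.07 (log2, SE; 32 exposed and 8 control animals; adjusted p = 6.9e-08), from a mean of 8.49 to 9.20, and was above control in 8 of 8 exposed groups. Pyroxd2 (0.53 ± 0.08, adjusted p = 4.4e-04), Gpd1 (0.52 ± 0.11, adjusted p = 0.040), the claudin-like Cldn34e (0.52 ± 0.10), the ATP-gated channel P2rx7 (0.42 ± 0.08, adjusted p = 0.011) and the TGF-beta co-receptor Tgfbr3 (0.34 ± 0.08) also rose. So did Tmem144 (0.36 ± 0.08), the focal adhesion gene Lims2 (0.29 ± 0.05), Lyrm1 (0.27 ± 0.04) and Adam1a (0.26 ± 0.05). These were above control in all 8 groups, except Gpd1, in 7. The 4 exposed groups of a sex shared their controls, so such tallies are not independent. Fcrl2 fell by 0.65 ± 0.11 (adjusted p = 0.0041; above control in 1 of 8 groups). The zinc transporter Slc39a12 fell by 0.42 ± 0.09, the polymerase subunit Polr3k by 0.32 ± 0.07, Cd93 by 0.31 ± 0.05 (adjusted p = 0.0035) and the serotonin receptor Htr1b by 0.16 ± 0.04, each below control in all 8 groups.

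In exposed Long Evans animals 2 immediate early genes fell and 5 probe sets of the myelin list rose. In the immediate early gene list, the nuclear receptor Nr4a1 fell by 0.42 ± 0.09 and the AP-1 subunit Junb by 0.31 ± 0.07 (both adjusted p = 0.040), while Arc, at -0.31 ± 0.07, did not pass (adjusted p = 0.064). The list mean was -0.19 over 24 probe sets, 2 fell and 15 did adjusted over the list alone, and its shift was called with an estimated correlation too (adjusted p = 0.036). In the myelin list the tight junction gene Cldn11 rose by 0.21 ± 0.04 (adjusted p = 0.0058), and the myelin glycoproteins Mog (0.26 ± 0.06) and Mag (0.21 ± 0.05) and the lipid enzyme Fa2h (0.25 ± 0.06) rose as well. All 17 probe sets of this list were positive, 5 passed and 14 passed adjusted over the list alone, with a mean of 0.17 and an adjusted p = 4.3e-23 that became 0.052 with an estimated correlation. Of the metal handling list, metallothionein Mt2A rose by 0.19 ± 0.04 (adjusted p = 0.048), but not with label numbers as a block (adjusted p = 0.051), and the list mean was 0.03 (adjusted p = 0.52 with an estimated correlation). The choroid plexus list mean was -0.25 and the meninges list mean was 0.15 in the same contrast.

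**Figure D4:**
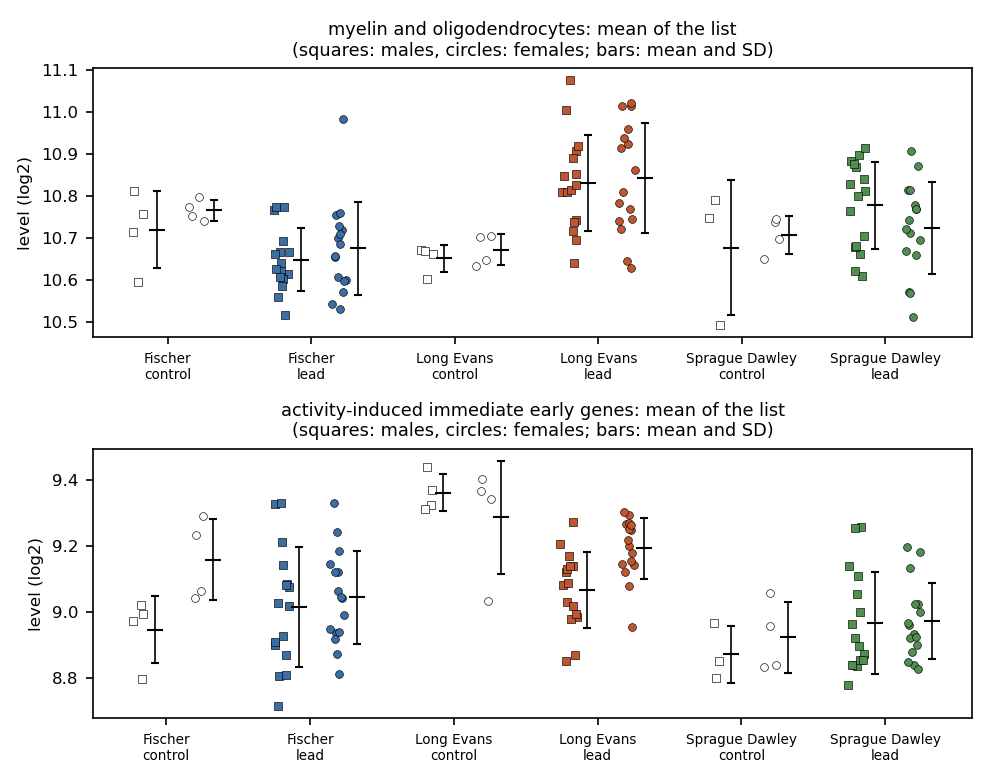
Mean level of the myelin list (upper panel) and of the immediate early gene list (lower panel) per array (y axes, log2) by strain and by control or lead (x axes), with squares for males, circles for females and bars for the mean and SD. Long Evans males had a myelin mean of 10.65 in controls and 10.83 after lead, and an immediate early gene mean of 9.36 in controls and 9.07 after lead.

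For the Long Evans mean, 62 probe sets were called (51 higher, 11 lower), of which 39 carried 1 symbol. Without the 3 Long Evans arrays against their sex label 15 were called (11 higher, 4 lower), 10 of them shared with the 62. Ldaf1 (adjusted p = 2.2e-05), Pyroxd2, Lims2, Lyrm1, Cd93, Nr4a1 and Junb kept their calls. Calls were lost for Fcrl2, Gpd1, Cldn34e, P2rx7, Tmem144, Tgfbr3, Adam1a, Slc39a12, Polr3k and Htr1b, for Cldn11, Mog, Mag and Fa2h of the myelin list, and for Mt2A (adjusted p from 0.078 for Fcrl2 to 0.36 for Mt2A). The mean of the immediate early gene list was then -0.25 (adjusted p = 0.016 with an estimated correlation) and that of the choroid plexus list -0.73. The count was 25 without male control 2, 29 without female control 4, 31 without male control 1, 32 without male control 3, 35 without female control 3, 37 without female control 2, 39 without male control 4 and 41 without male perinatal 750 ppm replicate 2. In the lower label numbers alone it was 2 and in the upper alone 3. Htr1b and Fa2h lost their calls with label numbers as a block (adjusted p = 0.054 and 0.051).

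In Sprague Dawley rats Serpina3n fell by 0.86 ± 0.09 in the mean of the 8 effects (log2, SE; 32 exposed and 7 control animals; adjusted p = 5.9e-07), from 6.74 to 5.88, and was below control in all 8 groups. Ifi27 rose by 0.44 ± 0.06 (adjusted p = 6.4e-04) and Fcrl2 by 0.58 ± 0.10 (adjusted p = 0.020), each above control in 8 of 8 groups. The other 2 of the 5 calls had no gene symbol and were chosen for mention after their values were seen, at -0.40 and -0.16. The count was 2 without female control 1 or 4 or male control 2, 3 without male control 1, 3 without the arrays against their sex label (Fcrl2 then had an adjusted p = 0.052), 0 in the lower label numbers alone and 2 in the upper alone. Immediate early genes had a list mean of 0.07 (adjusted p = 0.47 with an estimated correlation), the myelin list 0.06 (adjusted p = 0.47 with an estimated correlation) and the choroid plexus list 0.17.

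In Fischer rats the mean of the 8 effects gave 0 calls with limma, and 729 probe sets had an unadjusted p under 0.05. All 17 probe sets of the myelin list were negative, with a mean of -0.08 and an adjusted p = 4.6e-09 that became 0.20 with an estimated correlation. The interferon list had a mean of -0.08 with 1 call adjusted over the list alone (adjusted p = 0.20 with an estimated correlation). The meninges list had a mean of -0.18 and the choroid plexus list -0.10.

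**Figure D5:**
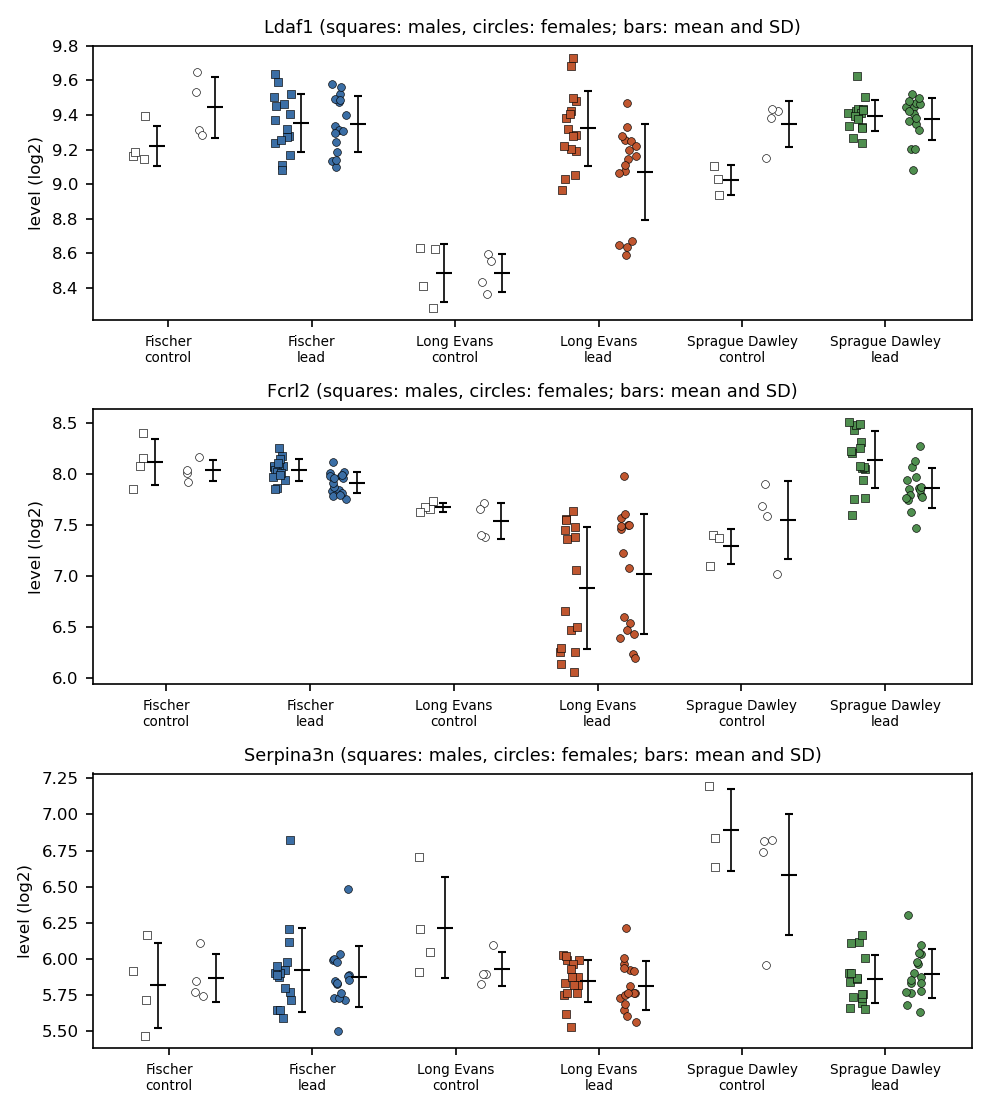
Levels of Ldaf1, Fcrl2 and Serpina3n per array (y axes, log2) by strain and by control or lead (x axes), with squares for males, circles for females and bars for the mean and SD. The highest Ldaf1 value among Long Evans controls was 8.628, while exposed Long Evans males lay between 8.965 and 9.73 and exposed females between 8.592 and 9.469.

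The levels behind these genes differed between the control groups as well. Ldaf1 averaged 8.49 in Long Evans male controls (SD 0.169, n = 4) and 8.49 in female controls (SD 0.108, n = 4), against 9.22 and 9.44 in Fischer controls and 9.02 and 9.35 in Sprague Dawley controls. Exposed Long Evans males averaged 9.32 (SD 0.216, n = 16) and exposed females 9.07 (SD 0.277, n = 16). Serpina3n averaged 6.89 in Sprague Dawley male controls (SD 0.282, n = 3) and 6.58 in female controls (SD 0.417, n = 4). Exposed Sprague Dawley animals averaged 5.86 and 5.90, and Fischer controls 5.82 and 5.87. Fcrl2 in exposed Long Evans animals had an SD of 0.598 in males and 0.590 in females, against means of 6.89 and 7.02. These animals fell into separate sets, from 6.065 to 6.657 and from 7.062 to 7.981, with none between. Long Evans controls lay between 7.383 and 7.737. All males at postnatal 750 ppm were in the lower set and all males at postnatal 250 ppm in the upper one. Females at perinatal 250 ppm were in both. The means hide this split, and what set these animals apart was not tested.

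The genes taken whatever their result, several of them long studied in lead toxicity, did not pass in any strain mean. For the heme synthesis enzyme Alad, which lead inhibits, the Fischer, Long Evans and Sprague Dawley means were -0.02, 0.03 and 0.03. For the NMDA receptor subunits they were 0.00, 0.03 and -0.01 (Grin1), -0.01, 0.04 and 0.00 (Grin2a) and 0.00, 0.02 and 0.01 (Grin2b). The neurotrophin Bdnf had -0.05, -0.07 and -0.03, the DNA methyltransferases Dnmt1 and Dnmt3a had 0.00, 0.05 and -0.01 and 0.01, 0.07 and -0.04, and the metallothioneins Mt1 and Mt3 had -0.08, 0.10 and -0.01 and -0.01, -0.01 and 0.00. Heme oxygenase Hmox1 had -0.06, 0.00 and 0.00, the astrocyte filament Gfap had -0.08, 0.01 and 0.09, and the choroid plexus gene Ttr had -0.28 ± 0.62, -0.42 ± 0.70 and 0.51 ± 0.64.

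Whether the mean lead effect differed between strains was tested directly. The Long Evans effect exceeded the Fischer effect by 0.69 ± 0.09 for Ldaf1 (log2, SE; adjusted p = 7.1e-08), 0.52 ± 0.08 for Pyroxd2 (adjusted p = 4.7e-05), 0.47 ± 0.08 for Lims2, 0.43 ± 0.09 for P2rx7 and 0.40 ± 0.09 for the growth factor Bmp4, and lay below it by -0.55 ± 0.13 for Fcrl2. The myelin list differed in the same contrast, with a mean of 0.26, all 17 probe sets positive, 8 called and 12 called adjusted over the list alone. Its shift was called with an estimated correlation (adjusted p = 4.9e-04), with label numbers as a block (0.0020) and without the arrays against their sex label (0.0022). Its members included Cldn11 (0.29 ± 0.05), the proteolipid Mal (0.37 ± 0.08), the galactolipid enzyme Ugt8 (0.40 ± 0.08) and Mag (0.29 ± 0.06). Mt2A, of the metal handling list, differed by 0.26 ± 0.06 (adjusted p = 0.045). The meninges list mean was 0.34 and the choroid plexus list mean -0.15. In all, 38 probe sets were called (34 higher, 4 lower), 84 with label numbers as a block, 4 and 8 in the lower and upper numbers alone, and 12 without the arrays against their sex label, 11 of them shared. P2rx7, Bmp4, Fcrl2, Mal, Ugt8, Mag and Mt2A lost their calls then (adjusted p from 0.099 to 0.48). The count was 21 without Long Evans female control 4, 23 without Fischer female control 1 and 24 without Fischer male control 4.

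Between Sprague Dawley and Fischer the lead effect differed for Serpina3n (-0.92 ± 0.12, adjusted p = 6.1e-07), Fcrl2 (0.68 ± 0.13, adjusted p = 0.032) and Ifi27 (0.46 ± 0.09, adjusted p = 0.032), which were the 3 calls. The myelin list was higher in all 17 probe sets, with a mean of 0.14 (adjusted p = 0.11 with an estimated correlation). The count was 1 without Fischer male control 1, 3 or 4, Fischer female control 4, Sprague Dawley male control 2 or Sprague Dawley female control 1 or 4, and 5 without Sprague Dawley female control 2. It was 5 with label numbers as a block, 0 and 1 in the lower and upper numbers alone, and 5 without the arrays against their sex label, which held all 3.

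Between Sprague Dawley and Long Evans the lead effect differed in both directions. Fcrl2 differed by 1.23 ± 0.13 (adjusted p = 3.6e-10), Dusp1 by 0.75 ± 0.17, Nr4a1 by 0.72 ± 0.12 (adjusted p = 5.9e-04), Arc by 0.65 ± 0.12 and Ifi27 by 0.48 ± 0.09. Cldn34e (-0.73 ± 0.14), Serpina3n (-0.62 ± 0.12), Pyroxd2 (-0.51 ± 0.08), Ldaf1 (-0.51 ± 0.09) and the filament linker Sync (-0.31 ± 0.06) had the lower values. The immediate early gene list had a mean of 0.27, with 21 of 24 probe sets positive, 5 called and 11 called adjusted over the list alone, among them Junb (0.41 ± 0.09) and the phosphatase Dusp6 (0.39 ± 0.07). Its shift was called with an estimated correlation (adjusted p = 7.1e-04), and also with label numbers as a block and without the arrays against their sex label (4.9e-04 and 0.0021). The choroid plexus list mean was 0.42 and the meninges list mean -0.20. The 23 calls (12 higher, 11 lower) became 42 with label numbers as a block, 9 and 6 in the lower and upper numbers alone, and 15 without Sprague Dawley male control 2. Without the arrays against their sex label 20 were called, 15 of them shared, and Cldn34e and Sync lost their calls (adjusted p = 0.099 and 0.16).

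Female and male lead effects were compared within each strain. Limma called 0 probe sets in Fischer and 0 in Long Evans, with 733 and 841 at an unadjusted p under 0.05, and 1 in Sprague Dawley, which had no gene symbol and was chosen for mention after its value was seen (-0.47 ± 0.08, adjusted p = 0.031). Without Fischer female perinatal 250 ppm replicate 1 the Fischer count was 1. The Sprague Dawley call was lost without female control 4, male control 1, 2 or 3 or any of 5 exposed animals, 2 were called without female control 3, and without the arrays against their sex label 1 other probe set was called. The list shifts called here, 14 of 84, were all lost with an estimated correlation; for example, the immediate early gene difference was 0.20 in Long Evans (adjusted p = 0.64 with an estimated correlation) and -0.18 in Fischer (adjusted p = 0.91 with an estimated correlation). Choroid plexus means differed by -0.75 in Fischer and 0.65 in Sprague Dawley. Across genes, which are not independent replicates, male and female effects of the same exposure correlated at -0.10 (Fischer, postnatal 750 ppm) to 0.27 (Long Evans, perinatal 250 ppm), and the latter was 0.43 among probe sets above the 40th percentile. Of calls with the same sign in both sexes, Long Evans had 1 at perinatal 250 ppm and 2 at each other exposure, with Tfcp2l1 and Ldaf1 the named ones at perinatal 750 ppm and Ldaf1 after both postnatal doses, and Fischer and Sprague Dawley had 0. Without the arrays against their sex label Long Evans had 0 at both perinatal doses and at postnatal 250 ppm and 1, with no gene symbol, at postnatal 750 ppm, while Sprague Dawley had 1, Serpina3n, at each exposure.

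Dose was compared as 750 minus 250 ppm over both sexes and periods. In Fischer rats genes induced by neuronal activity were higher at 750 ppm: Apold1 by 0.78 ± 0.09 (log2, SE; 16 animals per dose; adjusted p = 8.0e-06), the transcription factor Npas4 by 0.76 ± 0.14, Dusp1 by 0.69 ± 0.09 (adjusted p = 2.6e-05), Nr4a1 by 0.49 ± 0.08, Arc by 0.48 ± 0.08 and Fos by 0.44 ± 0.05 (adjusted p = 6.0e-06). The prostaglandin synthase Ptgs2 fell by 0.18 ± 0.03. The immediate early gene list was higher at 750 than at 250 ppm by a mean of 0.20. It had 9 called members (12 higher and 2 lower adjusted over the list alone) and an adjusted p = 0.042 with an estimated correlation. Controls averaged 8.946 in males and 9.159 in females. At perinatal and postnatal 250 ppm, males averaged 8.829 and 8.926 and females 8.971 and 8.994, all below their controls. At 750 ppm they averaged 9.098 and 9.207, and 9.005 and 9.211, so perinatal females lay below control too. The choroid plexus list was 0.59 higher (adjusted p = 0.34 with an estimated correlation) and the meninges list 0.21. Calls numbered 21 (16 higher, 5 lower), 65 with label numbers as a block, 0 and 4 in the lower and upper numbers alone, and 13 with the choroid plexus score as a covariate, where Npas4 lost its call (adjusted p = 0.069).

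In Long Evans rats 16 probe sets differed by dose (10 higher, 6 lower). The perinatal 750 ppm groups had label numbers far from those of the 250 ppm groups, so dose could not be told apart from such runs. The zinc finger gene Plagl1 rose by 0.41 ± 0.08, the receptor kinase Ret by 0.27 ± 0.05, the serotonin receptor Htr3a by 0.23 ± 0.05, the adhesion receptor Cd44 by 0.16 ± 0.03 and the complement receptor C5ar1 by 0.16 ± 0.03 (adjusted p from 0.013 to 0.040). The ion channel Tmem63a fell by 0.39 ± 0.06, Vom2r44 by 0.38 ± 0.07, Rpgr by 0.36 ± 0.05 (adjusted p = 0.0029), Rab7b by 0.27 ± 0.05 and the monoamine transporter Slc18a1 by 0.26 ± 0.04. C5ar1 lost its call with label numbers as a block (adjusted p = 0.051) and without the arrays against their sex label (0.057). The myelin list had a mean of -0.09 (adjusted p = 0.34 with an estimated correlation). The count was 30 without female perinatal 750 ppm replicate 1 and 30 with the choroid plexus score as a covariate, and 0 and 1 in the lower and upper numbers alone. In Sprague Dawley rats 1 probe set with no gene symbol, chosen for mention after its value was seen, was higher by 0.19 ± 0.03. Its call was lost without the arrays against their sex label, without any of 20 single animals, and in either label-number set alone; between 2 and 4 were called without female postnatal 250 ppm replicate 1, female perinatal 750 ppm replicate 4 or female perinatal 250 ppm replicate 4. With the choroid plexus score as a covariate 2 were called. Immediate early genes had a list mean of -0.07 there (adjusted p = 0.28 with an estimated correlation).

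Period was compared as postnatal minus perinatal exposure. In Long Evans rats the interferon-induced Ifit1 fell by 0.71 ± 0.11 (log2, SE; 16 animals per period; adjusted p = 0.0048), Vom2r44 by 0.34 ± 0.07, Popdc3 by 0.31 ± 0.06, the casein gene Csn1s2a by 0.19 and the kinase Prkd2 by 0.19 ± 0.04. The Fc receptor Fcgr2b rose by 0.24 ± 0.04, the decoy receptor Tnfrsf11b by 0.23 ± 0.05 and the monoamine transporter Slc29a4 by 0.21 ± 0.04, which lost its call with label numbers as a block (adjusted p = 0.052) and without the arrays against their sex label (0.057). The microglia list rose with a mean of 0.07, 17 of 21 probe sets positive, 1 called and 6 called adjusted over the list alone (adjusted p = 0.033 with an estimated correlation). The choroid plexus list was 0.86 higher (adjusted p = 0.30 with an estimated correlation), and with its score as a covariate the 19 calls (6 higher, 13 lower) became 3. Most of the genes named for this contrast thus lost their calls. Fewer were also called after a further quantile normalization and with array weights (given further below). The count was 2 without female postnatal 750 ppm replicate 4, male perinatal 250 ppm replicate 3 or 4, male perinatal 750 ppm replicate 1 or male postnatal 250 ppm replicate 4. It was 3 without female postnatal 750 ppm replicate 2 or male postnatal 750 ppm replicate 1, and 5 without female perinatal 250 ppm replicate 3, female perinatal 750 ppm replicate 3, female postnatal 250 ppm replicate 3 or male perinatal 750 ppm replicate 4. It was 8 without female perinatal 750 ppm replicate 4 or male postnatal 250 ppm replicate 2, 9 without female postnatal 250 ppm replicate 2, and 30 without male perinatal 250 ppm replicate 2. It was 0 and 1 in the lower and upper numbers alone.

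In Sprague Dawley rats the giant lipoprotein receptor Lrp1b was higher after postnatal exposure by 0.32 ± 0.06 and the potassium channel partner Kcnip1 by 0.21 ± 0.03 (adjusted p = 0.0011). Ccn1 fell by 0.49 ± 0.09, the p53 target Tp53inp1 by 0.37 ± 0.06 and Egr1 by 0.25 ± 0.05 (adjusted p = 0.011, 0.0056 and 0.049). The immediate early gene list had a mean of -0.12, with 1 called member and 11 adjusted over the list alone (adjusted p = 0.033 with an estimated correlation), while the choroid plexus list had a mean of -0.43. Immediate early genes averaged 9.18 in males and 9.11 in females at perinatal 250 ppm. They averaged 8.91 in both sexes at perinatal 750 ppm and from 8.84 to 8.97 in the postnatal groups. The list difference thus came from the perinatal 250 ppm groups. Of the 12 calls (9 higher, 3 lower) 10 were shared with the 14 found without the arrays against their sex label, where Ccn1 and Egr1 (adjusted p = 0.091 and 0.27) and the list (0.24 with an estimated correlation) did not pass. In either label-number set alone the count was 0. In Fischer rats Fos rose by 0.29 ± 0.05 (adjusted p = 0.026), the only call. There were 8 calls with label numbers as a block, 8 and 0 in the lower and upper numbers alone, 0 without any of 17 single animals, 2 without female postnatal 750 ppm replicate 4 and 6 without female perinatal 750 ppm replicate 3. Immediate early genes had a list mean of 0.11 (adjusted p = 0.22 with an estimated correlation).

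Control animals of the 3 strains differed in many probe sets, where sequence variants under the probes can give differences as well. Long Evans controls had higher levels than Fischer controls of the RNase P subunit Pop5 (2.07 ± 0.06, log2, SE; 8 against 8 animals; adjusted p = 9.1e-51), the olfactory receptor gene Or2b11 (1.49), Npas4 (1.38 ± 0.28), the histocompatibility gene RT1-N2 (1.24) and the synaptic organiser Cbln4 (1.20). They had lower levels of the epoxygenase Cyp2j4 (-1.39 ± 0.07, adjusted p = 4.9e-30), Pbld1 (-1.31), the sphingomyelin synthase Sgms2 (-1.16), the interferon-induced Ifi44l (-1.13) and Spetex2g (-0.97). Sprague Dawley controls exceeded Fischer controls in the serine protease Htra4 (2.48 ± 0.34), the neuropeptide Cartpt (1.22), Mei1 (1.15), Ccdc107 (1.14) and Nit2 (1.04), and were lower in RT1-M6-2 (-1.52), the epoxide hydrolase Ephx2 (-1.43), Cyp2j4 (-1.40), Scand1 (-1.34) and Akr1b10 (-1.33 ± 0.06). They exceeded Long Evans controls in Htra4 (2.41), Pbld1 (1.55), the invariant chain Cd74 (1.05), Nt5c3a (1.03) and Gpd1 (1.0), and were lower in Pop5 (-2.12 ± 0.06), Scand1 (-1.60), Akr1b10 (-1.51), Npas4 (-1.45) and Mx2 (-1.45).

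These strain contrasts gave 7328 calls for Long Evans against Fischer (3422 higher, 3906 lower), 3079 for Sprague Dawley against Fischer (1287 higher, 1792 lower) and 7148 for Sprague Dawley against Long Evans (3630 higher, 3518 lower). With label numbers as a block the count of the middle contrast rose to 4679, and in the upper numbers alone to 5466. In the lower numbers alone Long Evans against Fischer gave 3657, and in the upper numbers alone Sprague Dawley against Long Evans gave 4259. Without the arrays against their sex label the last contrast gave 4139.

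Between female and male controls limma called 0 probe sets, and 758 had an unadjusted p under 0.05. Eif2s3 was 0.32 higher in females, which did not pass (adjusted p = 0.12). Without the arrays against their sex label 3 were called, Eif2s3 (0.45 ± 0.06, adjusted p = 8.7e-06) and 2 with no gene symbol, chosen for mention after their values were seen (0.42 and 0.38). Those arrays were picked partly by Eif2s3 itself, so its larger difference without them follows from the rule and is no separate support. With label numbers as a block 2 were called, without Long Evans female control 3 there were 3, and without Fischer male control 3, Long Evans female control 1 or Long Evans male control 4 there were 2. Over all 30 groups, a contrast added after the data were seen, 45 probe sets differed (16 higher and 29 lower in females), 82 with label numbers as a block and 25 and 20 in the lower and upper numbers alone. The X-linked genes Eif2s3 (0.35 ± 0.03, adjusted p = 3.6e-16), Pbdc1 (0.27 ± 0.03) and Ddx3x (0.25 ± 0.04), the glucocorticoid-induced kinase Sgk1 (0.20 ± 0.04) and Trib1 (0.13 ± 0.03) were higher in females. Lower in females were the erythroid heme synthesis enzyme Alas2 (-0.48 ± 0.06, adjusted p = 2.4e-09), the globins Hbb-b1 (-0.47 ± 0.07) and Hbb (-0.45 ± 0.06), the globin chaperone Ahsp (-0.31 ± 0.06) and the lipoxygenase Alox15 (-0.49 ± 0.09).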

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

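The choroid plexus covariate was planned, but its use as a test of the Long Evans mean, and all 3 tests of the myelin list, were chosen after the results were seen, and the lists in strain differences, the label-number sets and the sex-label arrays were also taken up then.

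Fischer arrays differed between lower and upper label numbers in 17793 probe sets (60.9% of all; 5424 higher and 12369 lower in the upper numbers), and the highest of 99 other splits gave 1594, so chance can be excluded. The difference among controls followed that among exposed animals with a slope of 0.918 across genes, which argues against lead exposure, and 0.728 of the calls stayed after a further quantile normalization, which argues against overall scaling. With choroid plexus, meninges and red blood cell scores as covariates 0.779 of the calls stayed, which argues against those tissues. A processing difference that also parts Sprague Dawley arrays remained open, since their differences correlated across genes at -0.372 with those of Fischer, in the opposite direction. A batch of arrays or a shared day may be a candidate explanation, but the labels give neither, and the design names no biological difference between lower and upper numbers.

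The Long Evans mean lead effect called 62 probe sets, and of 100 splits 2, the real one included, gave as many. Such counts were thus rare when single animals were regrouped. The highest other, 101, exceeded the real count and points to a structure of the samples, so chance is not excluded. The choroid plexus score as covariate left a share of 0.935 of the 62 called, which argues against choroid plexus as the cause. Without the 3 arrays against their sex label the changes had a median ratio of 1.02 to the reported ones (0.773 to 1.26). All 62 kept their sign and 10 their call, with fewer controls. Those arrays helped choose the 62, so they are not excluded as the cause. Inherited variants stayed open: 3 pairs of called genes lay within 1 Mb of each other (Lyrm1 and Ldaf1, Camkk2 and P2rx7, Lims2 and Gpr17), against a median of 1 in 10000 random sets (permutation p = 0.14), and the within-group spread of the called genes in Long Evans over Fischer had a median ratio of 1.11, against 1.04 in random sets (permutation p = 0.094). Litter or family differences between the 8 controls and the exposed animals could therefore not be told apart from lead, and an effect of lead stays untested beyond the contrast itself.

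The myelin list was higher in the Long Evans than in the Fischer lead effect by 0.256. The list exceeded the mean of the astrocyte, microglia and blood vessel lists by 0.203 (interval 0.149 to 0.254, from resampling the probe sets of each list). This goes against a smaller share of neurons in these animals, but the interval leaves out the spread among animals, so that explanation is not excluded. Label numbers as a block gave an adjusted p = 0.0020 with an estimated correlation, but every Fischer and Long Evans group held as many lower as upper numbers, so the block could not move the change and decides nothing. A larger share of white matter in the dissected tissue had the values it needs, since the 5 brightest members (Mbp 0.19, Cldn11 0.29, Cnp 0.27, Mal 0.37, Mobp 0.27) had a median change at a ratio of 1 to that of the list. These data may therefore reflect dissection or more myelin per cell, and the second was not tested.

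The lead effect differed between strains, by tests of the difference itself, in 38 (Long Evans minus Fischer), 3 (Sprague Dawley minus Fischer) and 23 probe sets (Sprague Dawley minus Long Evans). Between sexes 1 was called (Sprague Dawley), a count that 11 of 100 splits reached, the real one included, so chance cannot be excluded for it. For Long Evans minus Fischer the named genes were Ldaf1 (0.692), Pyroxd2 (0.520), Lims2 (0.469), P2rx7 (0.429), Bmp4 (0.402) and Fcrl2 (-0.554). For Sprague Dawley minus Fischer they were Fcrl2 (0.680), Ifi27 (0.459) and Serpina3n (-0.915). For Sprague Dawley minus Long Evans they were Fcrl2 (1.23), Dusp1 (0.751), Nr4a1 (0.719), Arc (0.648), Ifi27 (0.475), Cldn34e (-0.733), Serpina3n (-0.617), Pyroxd2 (-0.509), Ldaf1 (-0.508) and Sync (-0.306). The immediate early gene list differed by 0.267 in that last contrast (controls differed more, as above).

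Single arrays far from the other 3 of their group were found in 19 of 261 tests of 9 measures chosen after their values were seen, where chance gives about 13 (about 1 in 20 groups). The choroid plexus score was low in Fischer male perinatal 750 ppm replicate 3 (7.554), Long Evans female control 1 (7.378) and Sprague Dawley female perinatal 250 ppm replicate 2 (8.477), and high in Long Evans female perinatal 250 ppm replicate 4 (9.32). The meninges score was low in Long Evans male perinatal 750 ppm replicate 3 (8.423) and male postnatal 750 ppm replicate 3 (8.292). The myelin score was low in Long Evans male control 3 (10.6), the immediate early gene score was low in Long Evans female control 3 (9.035), and the red blood cell score was high in Sprague Dawley female perinatal 250 ppm replicate 4 (8.271). Ldaf1 was high in Fischer male control 2 (9.394) and Long Evans female perinatal 250 ppm replicate 1 (9.074), and low in Long Evans female perinatal 750 ppm replicate 1 (8.65) and Sprague Dawley female perinatal 750 ppm replicate 1 (9.081). Fcrl2 was low in Fischer male perinatal 250 ppm replicate 1 (7.862) and Sprague Dawley female perinatal 250 ppm replicate 4 (7.472), and high in Fischer male postnatal 750 ppm replicate 3 (8.251). Serpina3n was high in Fischer male postnatal 750 ppm replicate 4 (6.821) and low in Sprague Dawley female control 2 (5.961). Eif2s3 was high in Long Evans male perinatal 250 ppm replicate 4 (11.43). Of these arrays, Long Evans female controls 1 and 3 and Sprague Dawley female control 2 also went against their sex label.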

How the results depend on the processing

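The label-number settings and the fits without the arrays against their sex label were chosen after the data were seen. Of 165 called results for named genes, 69 lost their call when some animal was left out and 0 changed sign. Among them 19 lost their call with array weights, 20 after quantile normalization, 17 with the choroid plexus covariate, 10 with label numbers as a block and 47 without the arrays against their sex label, and 0 reversed. Small changes were rarely called with 4 arrays per group: 17.9% of shifts of 0.25 simulated for Long Evans males at perinatal 250 ppm were. Fits on fewer animals have less power by construction, and for the other settings the cause was not tested. Exposures below stand in the order perinatal 250, perinatal 750, postnatal 250 and postnatal 750 ppm where no dose is named. Numbers are called probe sets, with those of the report in parentheses.

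With 1 fit for all arrays, Long Evans males had 40 (12), 26 (16), 11 (7) and 26 (14), and Long Evans females 12 (3) at perinatal 250, 13 (5) at postnatal 250 and 7 (3) at postnatal 750 ppm. Sprague Dawley males had 2 (4) at postnatal 250 and 10 (4) at postnatal 750 ppm, and females 4 (0) at perinatal 250 ppm. The Long Evans mean gave 118 (62) and the Sprague Dawley mean 8 (5). The sex difference gave 1 (0) in Fischer and 0 (1) in Sprague Dawley, dose 41 (16) in Long Evans and 5 (1) in Sprague Dawley, and period 0 (1) in Fischer, 55 (19) in Long Evans and 24 (12) in Sprague Dawley.

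With array weights, Fischer males had 7 (4) at postnatal 750 ppm and Fischer females 2 (1) at perinatal 250 ppm. Long Evans males had 7 (12) and 6 (16) after perinatal lead, and Long Evans females 10 (3), 76 (39), 13 (5) and 6 (3). Sprague Dawley males had 30 (8), 6 (3) and 14 (4) at perinatal 250, perinatal 750 and postnatal 750 ppm, and females 3 (0) and 1 (0) at perinatal 250 and postnatal 750 ppm. The Long Evans mean gave 104 (62), the Sprague Dawley mean 10 (5), Sprague Dawley minus Long Evans 59 (23), the Fischer sex difference 1 (0), dose 38 (16) in Long Evans and 2 (1) in Sprague Dawley, and period 6 (19) in Long Evans.

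After a further quantile normalization, Fischer females at perinatal 250 ppm had 2 (1), Sprague Dawley males 3 (8), 2 (4) and 2 (4) at perinatal 250, postnatal 250 and postnatal 750 ppm, the Sprague Dawley sex difference 0 (1), Sprague Dawley dose 2 (1), period 0 (1) in Fischer and 11 (19) in Long Evans, and control sex 2 (0). With the choroid plexus covariate, Fischer females at perinatal 250 ppm had 0 (1), Long Evans males at perinatal 750 ppm 6 (16), dose 13 (21) in Fischer, 30 (16) in Long Evans and 2 (1) in Sprague Dawley, and Long Evans period 3 (19). Above the 40th percentile of mean level, where fewer probe sets were tested, Long Evans males at postnatal 750 ppm had 8 (14), Sprague Dawley males 5 (8), 1 (3) and 2 (4) at perinatal 250, perinatal 750 and postnatal 750 ppm, the Sprague Dawley mean 3 (5) and the Sprague Dawley sex difference 0 (1). The correlation of male and female effects in Long Evans at perinatal 250 ppm became 0.43 (0.27).

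With label numbers as a block, Fischer males at postnatal 750 ppm had 9 (4), Fischer females at perinatal 250 ppm 2 (1), Long Evans females at perinatal 250 ppm 1 (3) and Sprague Dawley females at perinatal 250 ppm 2 (0). The strain differences gave 84 (38), 5 (3) and 42 (23) for Long Evans minus Fischer, Sprague Dawley minus Fischer and Sprague Dawley minus Long Evans. Fischer dose gave 65 (21), Fischer period 8 (1), Sprague Dawley minus Fischer controls 4679 (3079), control sex 2 (0) and the sexes over all groups 82 (45). In the lower numbers alone, the Long Evans mean gave 2 (62), the Sprague Dawley mean 0 (5), the strain differences 4, 0 and 9, dose 0 in every strain, period 8 in Fischer and 0 in Long Evans and Sprague Dawley, Long Evans minus Fischer controls 3657 (7328) and the sexes over all groups 25 (45). In the upper numbers alone, the Long Evans mean gave 3, the Sprague Dawley mean 2, the strain differences 8, 1 and 6, dose 4 in Fischer, 1 in Long Evans and 0 in Sprague Dawley, period 0, 1 and 0, Sprague Dawley minus Fischer controls 5466, Sprague Dawley minus Long Evans controls 4259 and the sexes over all groups 20.

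Without the arrays against their sex label, Long Evans males had 0 (16) at perinatal 750 and 3 (7) at postnatal 250 ppm, Long Evans females 0 (3), 5 (39), 1 (5) and 1 (3), Sprague Dawley males at perinatal 250 ppm 5 (8), and Sprague Dawley females 4, 2, 2 and 1 (each 0). The Long Evans mean gave 15 (62), the Sprague Dawley mean 3 (5), Long Evans minus Fischer 12 (38), Sprague Dawley minus Fischer 5 (3), Sprague Dawley dose 0 (1), Sprague Dawley minus Long Evans controls 4139 (7148) and control sex 3 (0). With an estimated correlation, called list shifts fell from 157 to 0 of 672 in the 24 contrasts and from 27 to 1 of 84 in the strain means.

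With each animal left out in turn, counts ranged from 1 to 6 in Fischer males at postnatal 750 ppm and from 0 to 2 in Fischer females at perinatal 250 ppm. In Long Evans males they ranged from 8 to 12, 0 to 13, 1 to 4 and 7 to 18, and in Long Evans females from 1 to 2, 16 to 41, 2 to 4 and 1 to 3. In Sprague Dawley males they ranged from 0 to 9, 1 to 5, 0 to 4 and 0 to 3, and in females from 0 to 4, 0 to 2, 0 to 2 and 0 to 2. The Long Evans mean ranged from 25 to 75 and the Sprague Dawley mean from 2 to 7. The strain differences ranged from 21 to 47, 1 to 5 and 15 to 30, and the sex differences from 0 to 1 in Fischer and 0 to 2 in Sprague Dawley. Dose ranged from 17 to 27 in Fischer, 11 to 30 in Long Evans and 0 to 4 in Sprague Dawley, period from 0 to 6, 2 to 30 and 8 to 17, and control sex from 0 to 3. Control strain contrasts ranged from 5842 to 7978, 2343 to 3186 and 5523 to 7278. The other 6 Fischer contrasts, the Fischer mean and the Long Evans sex difference stayed at 0.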

Other observations

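The list means by label number, the splits with label numbers as a block and the contrast of the sexes over all groups were chosen after the data were seen. Shifts of the gene lists over the 24 contrasts were small for synaptic genes: list means ranged from -0.05 to 0.04 for glutamate receptors (called higher in 1 contrast and lower in 2), -0.06 to 0.05 for the GABA system (0 and 1) and -0.03 to 0.04 for synaptic vesicle release (1 and 0). Glial and immune lists ranged from -0.15 to 0.26 for myelin (12 and 7), -0.06 to 0.09 for astrocytes (5 and 0), -0.07 to 0.07 for microglia (2 and 1) and -0.18 to 0.08 for interferon response (1 and 8). Immediate early genes ranged from -0.33 to 0.31 (4 and 10), glucocorticoid-induced genes from -0.16 to 0.26 (6 and 5) and the circadian clock from -0.04 to 0.10 (4 and 0). Stress lists ranged from -0.07 to 0.07 for metal handling (2 and 0), -0.07 to 0.07 for NRF2 (2 and 0), -0.08 to 0.15 for heme synthesis (1 and 0) and -0.13 to 0.06 for heat shock (3 and 5). DNA methylation and chromatin regulators ranged from -0.03 to 0.07, thyroid hormone targets from -0.12 to 0.17 and sex-chromosome genes from -0.08 to 0.09, each with 0 calls. Neurogenesis ranged from -0.07 to 0.06 (2 and 0), principal neurons from -0.08 to 0.02 (0 and 2), ribosomal proteins from -0.08 to 0.07 (8 and 6) and oxidative phosphorylation from -0.08 to 0.04 (3 and 6). With an estimated correlation 0 of these shifts were called in any contrast.

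Markers of tissue around the hippocampus also varied between groups. Over the same contrasts, list means ranged from -1.02 to 1.23 for choroid plexus (called higher in 5 and lower in 7), -0.50 to 0.43 for meninges (7 and 9), -0.35 to 0.47 for red blood cells (3 and 3) and -0.19 to 0.13 for blood vessels (2 and 5). Thalamus ranged from -0.12 to 0.18 (3 and 0), striatum from -0.10 to 0.12 (2 and 1) and neocortex from -0.07 to 0.09 (0 and 0). Of these shifts too, 0 were called with an estimated correlation. The extremes of choroid plexus were Long Evans females at perinatal 250 ppm (-1.02) and Sprague Dawley females at perinatal 250 ppm (1.23). In Fischer animals the upper label numbers had lower means than the lower numbers for meninges (-0.37), microglia (-0.17), immediate early genes (-0.15), neocortex (-0.15) and thalamus (-0.14), among others, and higher means for sex-chromosome genes (0.19), ribosomal proteins (0.16) and astrocytes (0.12), among others.

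Exposed animals whose label numbers ran on from those of their controls might have shared a day or litter with them. This was tested with the count of calls: if such runs mattered, contrasts within a run would have fewer calls than those across runs. The median ratio of within-run to across-run counts was 6.88, but it rests on 13 in Long Evans females and 0.75 in Sprague Dawley males, with 1 within-run contrast each. The 13 comes from the 39 calls at perinatal 750 ppm, which fell to 5 without the arrays against their sex label, where the other 3 exposures had 0, 1 and 1. These sets are too few to decide, and the explanation stays open.

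Other splits of the same animals gave the following. For the 24 contrasts all 35 splits of 4 against 4 animals, or of 4 against 3, were counted, the real one included. In Fischer males the real count of 4 at postnatal 750 ppm had 3 as the highest other (1 of 35 splits as large), while the other 3 contrasts gave 0 in the real split and 0 as the highest other. In Fischer females the real count of 1 at perinatal 250 ppm was reached by 3 of 35 splits, so chance cannot be excluded, and the split along label numbers gave 1084, which points to a structure of the samples. Their other 3 contrasts gave 0, with 1, 1 and 2 as the highest others. In Long Evans males chance cannot be excluded at perinatal 250 ppm (real 12, with 2 of 35 splits as large), where the highest other of 1698 also points to a structure of the samples. No other split gave as many at the other exposures (real 16, 7 and 14, against highest others of 1, 2 and 1). In Long Evans females none did at any of the 4 exposures (real 3, 39, 5 and 3, against 2, 9, 0 and 2). With 24 contrasts and shared controls, 1 of 35 splits does not exclude chance for a single contrast. In Sprague Dawley males the real counts of 8, 3, 4 and 4 had 3, 2, 1 and 0 as the highest others (1 of 35 splits as large in each). In Fischer and Sprague Dawley these free splits mix label numbers, and splits kept within the number sets are 18, too few for a share under 0.05. With label numbers as a block these gave 9 with 4 as the highest other (Fischer males, postnatal 750 ppm), 2 with 0 (Fischer females, perinatal 250 ppm), and 12 with 3, 3 with 1, 4 with 1 and 5 with 0 (Sprague Dawley males). In Sprague Dawley females all 35 splits gave at least the real 0, and the highest others were 9, 185, 2064 and 20. The 185 and 2064 point to a structure of the samples. The split along label numbers gave 0 in each of these contrasts, and that structure was not identified.

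For the pooled contrasts 100 splits were drawn, the real one included. All splits regrouped single animals, so differences between litters, which the labels do not give, were not tested. The mean effect in Sprague Dawley had a real count of 5 and 1 as the highest other, and the Fischer mean had a real count of 0 and a highest other of 634, again a structure of the samples. In Long Evans, dose had a real count of 16 with 25 as the highest other (2 of 100 splits as large). Period there had 19 with 20 (2 of 100). Such counts were rare, but another split exceeded each, so chance is not excluded. In the other strains the free splits mix label numbers: dose gave 21 with 1 in Fischer and 1 with 14 in Sprague Dawley, and period 1 with 8 in Fischer and 12 with 3 in Sprague Dawley. With label numbers as a block and splits within the number sets, no other split gave as many for dose in Fischer (65 with 4) or period in Sprague Dawley (13 with 9). Other splits exceeded period in Fischer (8 with 524, in 2 of 100) and the Sprague Dawley mean (4 with 322, in 3 of 100). The 524 and 322 point to a further structure of the samples, so chance is not excluded for these. Sprague Dawley dose gave 1 with that block, with 1 as the highest other (in 2 of 100), a single call that many left-out animals ended. For the strain differences no other split gave as many calls (38 with 34 as the highest other, 3 with 2, and 23 with 3). With label numbers as a block and splits within the number sets this held for Long Evans minus Fischer (84 with 15). Other splits exceeded Sprague Dawley minus Fischer (5 with 90, in 3 of 100) and Sprague Dawley minus Long Evans (42 with 43, in 2 of 100). The 90 points to a structure of the samples. Sex differences of the lead effect gave 0 (highest other 0), 0 (7) and 1 (2, in 11 of 100 splits as large), where chance cannot be excluded for the last. Control strain contrasts (7328 with 1924, 3079 with 1244 and 7148 with 2156) and the sexes over all groups (45 with 2) were beyond chance, and the control sex contrast gave 0 with 1 as the highest other.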
